A study of Mus musculus with 8 samples.

How the data were processed

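Optic fissure tissue was collected by laser capture microdissection from frozen sections of wild-type C57BL/6 mouse embryos, and lysates of 3 embryos of one stage were pooled per array, per the labels. One label gives the pooled embryos as coming from a single litter and the extraction protocol as coming from separate litters, and this conflict was left open. RNA was amplified linearly by repeated in vitro transcription and labelled with biotin, per the labels' protocols. Such amplification can differ between arrays and favours the 3 prime ends of transcripts. The labels call the arrays of a stage biological replicates, 3 at E10.5, 3 at E11.5 and 2 at E12.5, and the letters A to C of the sample titles name them.

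The deposited table holds log2 values, 1 per probe set and array, for 45101 probe sets. GCOS 1.4 is named in the submitters' processing notes, with no role given. How probes were summarized, background was removed and arrays were normalized is not given in the sources used here. The array medians lie close together while the upper ends of the ranges differ, so the deposited values are not quantile normalized across arrays. No detection calls were used, and the strength of a signal over background is known only from its log2 value.

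The 64 control probe sets were left out, and so was every probe set in the lowest 40% by mean log2 signal over the 8 arrays (below 3.94), which kept 27022. Gene names came from the platform's annotation of 2016, in which 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Of those with 1, 34754 matched the gene identifiers of a RefSeq table of assembly GRCm38.p6, used for names only. The kept probe sets with 1 gene numbered 22650 and covered 13050 genes, and none was named from a probe set with several. Some probe sets, such as those of Rab38 and Hes5, carry the manufacturer's suffix for probes that can also match other transcripts. Certain genes are not reported here.

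The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with no further normalization, in 1 linear model of stage over all 8 arrays, which share 1 estimate of spread (5 residual degrees of freedom). Standard errors and two-sided p-values came from empirical Bayes moderation with a trend on mean signal. The comparisons were E11.5 with E10.5, E12.5 with E11.5, E12.5 with E10.5, E11.5 with the mean of the other stages, and an F test for any stage difference. P-values were adjusted by Benjamini-Hochberg over the kept probe sets, with a threshold of 0.05. Fold changes are differences of stage means on the log2 scale. They understate changes of genes near the lower end of the signal range.

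There were 38 gene lists with 985 symbols, of which 734 had a kept probe set, and 36 lists with at least 5 kept genes were tested. Each gene was represented by its kept probe set with the highest mean signal. Camera in limma, with a preset correlation of 0.01, set each list against all other genes, with Benjamini-Hochberg adjustment over the 108 tests of 36 lists in 3 comparisons. Of 41 called tests, 0 held with the correlation estimated from the data. A count given as adjusted over the list alone used Benjamini-Hochberg over that list's genes only. A rotation test (fry), which asks whether a list's genes move one way on balance, was run beside it.

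The design, the lists and the alternatives below were fixed before the data were examined, as was the rule for naming genes, and 2 alternatives were added afterwards (2 arrays left out together, array weights gene by gene). The rule took the 10 largest rises and the 10 largest falls per pairwise comparison among called probe sets with 1 gene and no overlap between the arrays of the stages compared, or all where fewer passed. It took 5 each way for the middle-stage contrast, the genes tied to fissure closure as values, and for each list up to 4 genes with the smallest p. A named gene's change is that of 1 probe set, and other probe sets of the same gene were not always called.

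The fit was tested on simulated values for 27022 probe sets with the real means and spreads. Each value was drawn independently, with none of the array-wide differences that the real arrays show. The rates below therefore hold for such values and can be too favourable for the real ones. With 50 probe sets changed at each size, the comparison of E11.5 with E10.5 recovered 26% of 2-fold, 84% of 4-fold and 100% of 8-fold changes with 7 false calls. That of E12.5 with E11.5 recovered 24%, 76% and 94% with 4 false calls, and that of E12.5 with E10.5 recovered 20%, 76% and 98% with 2 false calls. With no list changed, camera called 0 of 108 tests in simulated values, whose genes are independent. With the retinal neurogenesis list raised 2-fold at E12.5, it called 3 tests, of which 1 was of another list.

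Alternatives were quantile normalization, median centring of arrays, pseudocounts of 1 and 64 added on the linear scale, no filter and a filter of the lowest 60%, no trend in the prior, array weights, the replicate letter as a block, the 3 to 5 prime difference of the Gapdh control as a covariate, fits of 2 stages only, and leaving out each array in turn. For lists, an estimated correlation, fry and the mean of a gene's probe sets were also tried. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.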

Results

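The series followed gene expression in the optic fissure of the mouse embryo, the ventral groove of the optic cup whose edges meet and close during eye development. Fissure tissue was cut by laser capture from frozen sections of wild-type C57BL/6 embryos at embryonic days 10.5, 11.5 and 12.5. There were 3 arrays at E10.5, 3 at E11.5 and 2 at E12.5, named here by stage and by the letters A to C, and each array held RNA pooled from 3 embryos. The table gave log2 signals, of which 27022 probe sets were tested, and the 8 array medians lay between 4.37 and 4.48. The upper end of the signal range differed more. The 99th percentile of log2 signal was 12.8 ± 0.21 (SD, n = 3) at E10.5, 11.8 ± 0.60 (SD, n = 3) at E11.5 and 12.5 ± 0.08 (SD, n = 2) at E12.5. In an exact two-sided permutation test of E10.5 against E11.5 this gave p = 0.10, the smallest p that 3 arrays against 3 allow. The 3 prime minus 5 prime log2 signal of the Gapdh control, a measure of how complete the amplified transcripts are, was 4.47 ± 0.26 (SD, n = 3) at E10.5, 3.97 ± 0.64 (SD, n = 3) at E11.5 and 4.97 ± 0.27 (SD, n = 2) at E12.5. It was at most 4.63 on an E11.5 array and at least 4.78 on an E12.5 array, and for Actb these limits were 6.61 and 6.88. The arrays of these stages thus did not overlap in this measure of RNA quality. For Actb it was at least 6.83 on an E10.5 array, also above every E11.5 array (p = 0.10 in the same permutation test). For Gapdh it was at most 4.71 on an E10.5 array, below both E12.5 arrays. Each pair of stages is thus partly confounded with RNA quality in 1 or both controls. On the first 2 principal components, with 39.3% and 29.4% of the variance, E10.5 C (-81.6 on the first) and E11.5 A (-80.8 on the second) lay farthest from the other arrays of their stages. The small number of arrays limits the precision of every value below.

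Some genes of melanin synthesis and some of the periocular mesenchyme rose in the fissure between E10.5 and E11.5, 4 of 22 and 3 of 20 measured. Tyr, tyrosinase, the rate-limiting enzyme of melanin synthesis, rose from a log2 signal of 3.77 ± 0.61 (SD, n = 3) to 8.55 ± 0.88 (SD, n = 3), a log2 change of 4.78 (SE 0.42, 27.6-fold, adjusted p = 0.00159). Gpr143, a receptor of the melanosome membrane, rose by 2.73 (SE 0.33, adjusted p = 0.0143), and Rab38, a small GTPase that carries cargo to melanosomes, rose by 2.22 (SE 0.32, adjusted p = 0.0318). Oca2, a melanosomal membrane transporter, rose by 2.13 (SE 0.34, adjusted p = 0.0401). These were 4 of the 22 measured genes in the list of retinal pigment epithelium and melanin synthesis, with 18 not passing and none falling. Adjusted over the list alone, 12 were higher. The list's median log2 change was 1.06 against -0.22 for the median of all 13050 genes, and camera called it higher (adjusted p = 2.4e-14, but adjusted p = 0.332 with an estimated correlation). Relative to all genes the shift was 1.28, and 1.24 after quantile normalization.

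In the list of periocular mesenchyme, the neural crest and mesodermal tissue around the eye, 3 of 20 measured genes rose and 17 did not pass. Ogn, the small matrix proteoglycan osteoglycin, rose by 3.82 (SE 0.43, adjusted p = 0.00893) from a log2 signal of 3.10 ± 0.01 (SD, n = 3) at E10.5. Postn, the matrix protein periostin, rose by 3.15 (SE 0.51, adjusted p = 0.0401), and Dcn, the collagen-binding proteoglycan decorin, rose by 1.48 (SE 0.23, adjusted p = 0.0359). Adjusted over the list alone, 11 were higher. The median change was 0.97 (camera adjusted p = 6.9e-15, but adjusted p = 0.326 with an estimated correlation), or 1.18 relative to all genes and 1.01 after quantile normalization. Other matrix genes that rose were Col8a1, a short-chain collagen, by 3.95 (SE 0.39, adjusted p = 0.0024), Pcolce, an enhancer of procollagen processing, 5.67-fold (log2 SE 0.40, adjusted p = 0.0401), and Npnt, the integrin ligand nephronectin, by 2.14 (SE 0.33, adjusted p = 0.0359). Npnt was the single called gene of 32 in the list of basement membrane and core matrix (3 higher when adjusted over the list alone). That list was called higher (adjusted p = 0.0184, adjusted p = 0.799 with an estimated correlation), although its median was -0.13 and its mean 0.09, and its median turned to 0.21 after quantile normalization. Cryab, a small heat shock protein abundant in lens, rose by 3.89 (SE 0.36, adjusted p = 0.00159). It was the single called gene of the 14 measured lens markers, of which 2 were higher when adjusted over the list alone, and the lens median was -0.10 with the list not called. Pcp4, a calmodulin-binding peptide of neurons, rose by 4.03, and Bace2, a protease that acts on a melanosome protein, rose by 2.20. Rab38, Col8a1 and Pcolce were called on 1 of 2 probe sets each, Tyr on 2 of 3 and Bace2 on 2 of 5, with the others of the same sign.

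As deposited, fewer genes fell than rose from E10.5 to E11.5, and they changed less. Sall4, a zinc finger factor of pluripotent and early embryonic cells, fell by 1.54 (SE 0.22, adjusted p = 0.0318) on 1 of its 2 probe sets, with the other lower but not called. Nkx6-1, a homeodomain factor of the ventral neural tube, fell by 1.72 (SE 0.26, adjusted p = 0.0359), and Scube2, a secreted protein that helps release hedgehog ligands, fell by 1.64 (SE 0.26, adjusted p = 0.0401). Nr2f2, a nuclear receptor, fell by 1.33 (SE 0.20, adjusted p = 0.0359) on 1 of its 6 probe sets, with the other probe sets lower but not called. Lmo3, a LIM domain protein, fell by 1.52, and Eno4, an enolase family member, fell by 1.48 on 1 of its 3 probe sets, with the others lower but not called.

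Lists of cell cycle, ribosomal and metabolic genes were lower at E11.5 as deposited, beside the lower upper end of the signal range on those arrays. The 51 cell cycle genes had a median of -0.84, with 0 called by limma over all probe sets and 37 lower, 1 higher, adjusted over the list alone (camera adjusted p = 7.39e-10, adjusted p = 0.564 with an estimated correlation). Relative to all genes this was -0.62, and -0.27 after quantile normalization, with the list still called. The 20 cholesterol synthesis genes had a median of -0.59 and 0 called, 4 lower adjusted over the list alone (adjusted p = 0.0045, adjusted p = 0.645 with an estimated correlation), or -0.37 relative to all genes and -0.23 after quantile normalization. The 26 ribosomal protein genes (median -0.87, adjusted p = 0.000139, adjusted p = 0.799 with an estimated correlation) and the 34 oxidative phosphorylation genes (median -0.77, adjusted p = 4.86e-05, adjusted p = 0.799 with an estimated correlation) had 0 called genes, and 0 and 8 lower adjusted over each list alone. Quantile normalization brought these medians to -0.06 and -0.04 and ended both calls (adjusted p = 0.335 and 0.905). Markers of other cell types that captured tissue can hold were called higher with small medians. These were 0.18 for 19 macrophage and microglia genes (adjusted p = 3.73e-05, adjusted p = 0.332 with an estimated correlation), 0.13 for 14 erythroid genes (adjusted p = 0.00162, adjusted p = 0.332 with an estimated correlation), 0.09 for 15 endothelial genes (adjusted p = 0.00656, adjusted p = 0.483 with an estimated correlation) and 0.30 for 7 surface ectoderm genes (adjusted p = 0.0101, adjusted p = 0.332 with an estimated correlation). None of these markers was called singly by limma over all probe sets. Adjusted over each list alone, 0 macrophage, 4 erythroid (with 1 lower), 0 endothelial and 1 surface ectoderm gene were higher. The endothelial and surface ectoderm calls ended after quantile normalization (adjusted p = 0.115 and 0.105). The 31 matrix proteases and inhibitors were called higher with a median of -0.05 and a mean of 0.05 (adjusted p = 0.0115, adjusted p = 0.332 with an estimated correlation), with 0 called singly and 3 higher adjusted over the list alone, and that call ended after quantile normalization (adjusted p = 0.0651), where the median was 0.15.

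In all, 34 of 27022 probe sets passed between E10.5 and E11.5 in limma at an adjusted p below 0.05, 26 higher (23 genes) and 8 lower (6 genes), against 5254 at an unadjusted p below 0.05. The share that was higher was 76.5% as deposited and 91.3% after quantile normalization, which moved the median change of all probe sets from -0.18 to -0.02. It was 57.1% without E10.5 A, and with array weights, which rest mainly on E11.5 B, most calls were lower instead, with 23.3% and 24.3% (gene by gene) higher. The count rested on single arrays and on the scale of the values. It was 5 without E11.5 B, 9 without E11.5 C, 56 without E11.5 A, 15 without E12.5 A, 14 without E12.5 B and 0 with a pseudocount of 64. Of the 16 called probe sets named as the largest rises and falls in this comparison, 3 (Tyr, Col8a1 and Cryab) stayed called whichever array was left out. Genes named only as list members, such as Oca2, Dcn and Npnt, were not followed in these fits. Every one of the 6 falls was lost in more than 1 such fit. Without E11.5 B, Ogn, Gpr143 and Rab38 were no longer called, nor were Postn, Pcolce, Pcp4 or Bace2.

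Between E11.5 and E12.5 some genes that start retinal neurogenesis, such as Atoh7 and Neurog2, rose from near the lower end of the signal range to high levels. Atoh7, the factor needed for retinal ganglion cells to form, rose from a log2 signal of 3.68 ± 0.07 (SD, n = 3) to 11.99 ± 0.74 (SD, n = 2), a change of 8.30 (SE 0.29, 316-fold, adjusted p = 7.69e-08). Neurog2, a proneural factor, rose by 6.89 (SE 0.34, adjusted p = 1.52e-06), and Neurod1, a factor of differentiating neurons, rose by 5.89 (SE 0.26, adjusted p = 5.69e-07). Insm1, a zinc finger factor of newborn neurons, rose by 6.23 (SE 0.45, adjusted p = 3.02e-05), and the Notch ligand Dll1 rose by 3.87 (SE 0.27, adjusted p = 2.91e-05). In the neurogenesis list 17 of 32 measured genes rose, 15 did not pass and none fell. Adjusted over the list alone, 26 were higher and 1 was lower. The median log2 change was 2.60 (camera adjusted p = 7.35e-19, adjusted p = 0.397 with an estimated correlation), or 2.49 relative to all genes and 2.55 after quantile normalization. Nefl, the light neurofilament subunit of axons, rose by 5.46 (SE 1.09, adjusted p = 0.0292) on 1 of its 2 probe sets, with the other higher but not called. The error was wide, since the called probe set read 7.24 on E12.5 A and 12.7 on E12.5 B. The 2 arrays differed across the list, with 30 of the 32 genes higher on E12.5 B, 21 of them by more than 1, and a median difference of 1.24. From E10.5 to E11.5 this list had a median of -0.13 and a mean of 0.01, with 0 of 32 called and 1 higher adjusted over the list alone. Camera nevertheless placed it above other genes there (adjusted p = 0.0261, adjusted p = 0.881 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.877).

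**Figure D1:**
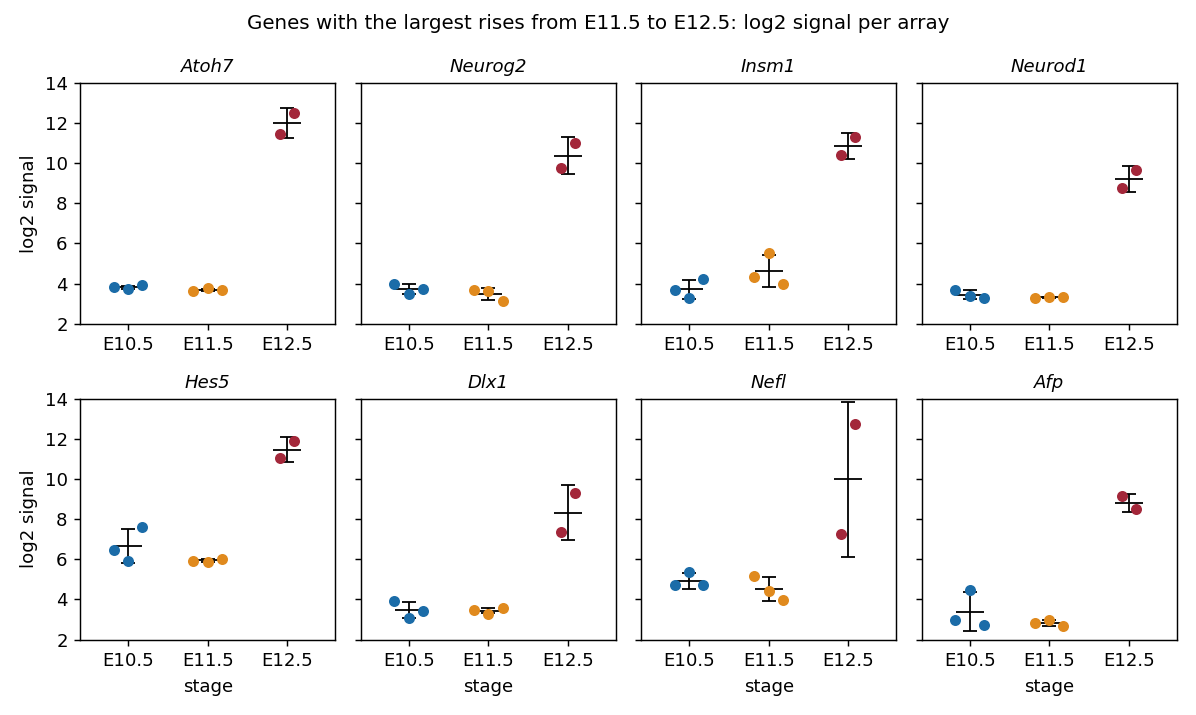
Log2 signal (vertical axis) of 8 of the genes with the largest rises from E11.5 to E12.5, by stage (horizontal axis), with 1 point per array and bars for the mean ± SD of 3, 3 and 2 arrays. Atoh7 lies below 4 on all 6 earlier arrays and at 11.5 and 12.5 on the E12.5 arrays, and Nefl differs most between the 2 E12.5 arrays.

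Some genes of retinal progenitors and of Notch signalling rose in the same interval. The lists share members, so their counts are not independent. Hes5 and Notch1 are in both of these lists, and Dll1 and Hes6 are in the neurogenesis and Notch lists. Gadd45g and Btg2 are in the neurogenesis and cell cycle exit lists. Fgf15 is also an FGF list member, and Sfrp2 and Fzd5 are in the progenitor and Wnt lists. Hes5, a Notch effector that holds cells in the progenitor state, rose by 5.51 (SE 0.43, adjusted p = 5.74e-05), and Fgf15, a growth factor of the progenitor zone, rose by 3.79 (SE 0.38, adjusted p = 0.000416). Rorb, a nuclear receptor of retinal progenitors, rose by 2.53 (SE 0.39, adjusted p = 0.00679), and the receptor Notch1 rose by 1.76 (SE 0.30, adjusted p = 0.0122). Of the 24 measured progenitor genes, 10 rose, 14 did not pass and none fell (18 higher adjusted over the list alone). Their median was 1.22 (camera adjusted p = 2.36e-09, adjusted p = 0.514 with an estimated correlation), or 1.11 relative to all genes and 0.67 after quantile normalization. Of 21 Notch pathway genes 9 rose and 12 did not pass (10 higher adjusted over the list alone, median 0.71, adjusted p = 4.38e-05, adjusted p = 0.535 with an estimated correlation). They included Mfng, a glycosyltransferase that modifies Notch, at 2.66 (SE 0.36, adjusted p = 0.00314) and Hes6 at 2.48 (SE 0.36, adjusted p = 0.00482). Of 12 measured genes in the cell cycle exit list 5 rose and 7 did not pass (8 higher adjusted over the list alone, median 1.24, adjusted p = 3.45e-05, adjusted p = 0.332 with an estimated correlation). The largest of these rises was Gadd45a, a stress and growth arrest gene, at 4.25 (SE 0.36, adjusted p = 0.00012). The cell cycle list was also higher (median 0.62, adjusted p = 4.86e-05, adjusted p = 0.767 with an estimated correlation), with 1 of 51 genes called, the cyclin Ccne2 at 1.70 (SE 0.30, adjusted p = 0.0155). That gene was also the single one higher adjusted over the list alone, and the list's median relative to all genes was 0.51, or 0.25 after quantile normalization.

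Some FGF pathway genes rose in this interval, and Wnt pathway genes moved both ways. Of 19 FGF pathway genes 3 rose and 16 did not pass (6 higher adjusted over the list alone, median 0.75, adjusted p = 0.0157, adjusted p = 0.564 with an estimated correlation). Besides Fgf15 these were the transcriptional target Etv5, at 1.67 (SE 0.23, adjusted p = 0.00313), and the ligand Fgf9, at 2.12 (SE 0.43, adjusted p = 0.032). Of 37 Wnt pathway genes, Dkk1, a secreted inhibitor of Wnt receptors, fell by 2.82 (SE 0.42, adjusted p = 0.00585), while Dkk3, Sfrp2 and the receptor Fzd5 rose by 2.61, 2.06 and 2.05. Adjusted over the list alone 6 were higher and 6 lower. The Wnt list's median was -0.10 and its lower call (adjusted p = 0.0453, adjusted p = 0.791 with an estimated correlation) ended after quantile normalization (adjusted p = 0.317). In the list of cell adhesion genes 6 of 37 rose and none fell, with 8 higher adjusted over the list alone, and the list was not called (adjusted p = 0.275). They included the protocadherins Pcdh8 and Pcdh19, at 3.24 (SE 0.48, adjusted p = 0.00497) and 2.89 (SE 0.43, adjusted p = 0.00523), and the integrin Itgb8 at 1.91 (SE 0.29, adjusted p = 0.00666).

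Other rises were Afp, alpha-fetoprotein, the main serum protein of fetal liver and yolk sac, by 5.98 (SE 0.42, adjusted p = 2.91e-05), from 2.83 ± 0.15 (SD, n = 3) to 8.81 ± 0.45 (SD, n = 2), with its 3 probe sets all called. Dlx1, a homeodomain factor of developing retina and forebrain, rose by 4.89 (SE 0.43, adjusted p = 0.000161). The netrin receptor Dcc rose by 4.39 (SE 0.56, adjusted p = 0.0021) on 2 of its 3 probe sets and did not pass, with opposite sign, on the other. Rassf4, a Ras association domain protein, rose by 4.34 (SE 0.49, adjusted p = 0.000859). Among the genes that fell, Hbb-bh1, the embryonic beta-like hemoglobin of primitive red cells, fell by 3.06 (SE 0.48, adjusted p = 0.00755). It was the single called gene of 14 erythroid markers (4 lower adjusted over the list alone), a list with a median of -0.10 (adjusted p = 0.00321, adjusted p = 0.365 with an estimated correlation). Afap1l2, an actin filament-associated adaptor, fell by 3.39 (SE 0.39, adjusted p = 0.000916) on 1 of its 2 probe sets, with the other lower but not called. Cplx3, a complexin of synaptic vesicle release, fell by 2.87 (SE 0.33, adjusted p = 0.00103). Car3, a carbonic anhydrase, fell by 2.43, Crym, a thyroid hormone-binding protein, by 2.48, Inmt, a methyltransferase, by 2.35 and Crispld2, a secreted protein, by 2.24. Crispld2 was called on 1 of its 3 probe sets, with the others lower. The 13 markers of telencephalon and hypothalamus were not called as a list (adjusted p = 0.645, median -0.06, mean 0.52), and Dlx1 and Isl1 were its 2 called genes, also the 2 that were higher adjusted over the list alone (with 1 lower).

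Lists called lower between E11.5 and E12.5 held few or no called genes. The 12 cartilage genes had a median of -0.43 (adjusted p = 0.000358, adjusted p = 0.535 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone. The 24 hypoxia and glycolysis genes had -0.15 (adjusted p = 0.0109, adjusted p = 0.799 with an estimated correlation), again with 0 and 1. The 22 pigment epithelium genes had -0.09 (adjusted p = 0.024, adjusted p = 0.798 with an estimated correlation), with 0 called, 1 higher and 3 lower adjusted over the list alone. Quantile normalization ended the calls of 10 pericyte genes (median -0.12, adjusted p = 0.0294, adjusted p = 0.591 with an estimated correlation), 9 Hox genes (-0.16, adjusted p = 0.0294, adjusted p = 0.591 with an estimated correlation) and 31 matrix proteases (-0.17, adjusted p = 0.0277, adjusted p = 0.332 with an estimated correlation). These had 0 called genes, and 2, 0 and 0 lower adjusted over each list alone.

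In all, 492 probe sets passed between E11.5 and E12.5, 438 higher (314 genes) and 54 lower (44 genes), against 4507 at an unadjusted p below 0.05. The share that was higher was 89.0% as deposited and 67.6% after quantile normalization, which moved the median change of all probe sets from 0.10 to -0.04. The count was 114 without E12.5 B, 184 without E11.5 A, 203 without E11.5 B, 322 without E10.5 B, 849 without E10.5 C and 905 without E11.5 C, and it was 73 with the Gapdh 3 to 5 prime difference as a covariate. That difference was larger on both E12.5 arrays than on any E11.5 array, so the changes of this comparison are partly confounded with RNA quality. The other pairs of stages are so in 1 of the 2 controls. Of 24 called probe sets of the named genes, 14 stayed called whichever array was left out, among them those of Atoh7, Neurog2, Neurod1, Insm1, Hes5, Afp, Dlx1, Dcc, Rassf4, Afap1l2, Cplx3 and Ntn1 and both of Cdh4. Leaving out an E12.5 array leaves 1, so the spread between the 2 E12.5 arrays does not enter those fits. The 24 were of the largest rises and falls and the fissure closure genes. Genes named only as list members, such as Dll1 and Rorb, were not followed. Dlx1 read 7.37 on E12.5 A and 9.29 on E12.5 B, Dcc 7.2 and 9.7, and Rassf4 8.75 and 10.73. Nefl was lost without E10.5 B or any 1 of the E11.5 arrays. Without E12.5 B, Hbb-bh1 (adjusted p = 0.187), Dkk1 (adjusted p = 0.11), Car3, Crym, Inmt, Crispld2 and Zfp503 were no longer called. Crispld2 was also lost without E11.5 A or E11.5 B, Crym without E11.5 A, and Inmt without E11.5 B or E11.5 C.

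From E10.5 to E12.5 Atoh7, Tyr and Ogn were among the genes with the largest rises, and Ntn1, Dkk1 and Fst were among those with the largest falls. Tyr was higher by 5.61 (SE 0.47, adjusted p = 8.19e-05), Ogn by 5.48 (SE 0.49, adjusted p = 0.000103) and Atoh7 by 8.17 (SE 0.29, adjusted p = 9.2e-08). Ntn1, the secreted guidance and adhesion protein netrin, fell by 4.04 (SE 0.30, 16.4-fold, adjusted p = 3.57e-05). Fst, the activin and BMP antagonist follistatin, fell by 2.87 (SE 0.38, adjusted p = 0.00166), and Dkk1 fell by 3.10 (SE 0.42, adjusted p = 0.00208). Dusp9, a phosphatase that acts on MAP kinases, fell by 2.92 (SE 0.38, adjusted p = 0.00133), Hmga2, a chromatin protein of early progenitors, by 2.79 (SE 0.53, adjusted p = 0.0132), and Cdh6, a cadherin, by 2.73 (SE 0.44, adjusted p = 0.00535). Hmga2 was called on 1 of 3 probe sets and Cdh6 on 1 of 2, with the others lower. Eif4ebp1, a repressor of translation initiation, fell by 2.75 on 2 of its 3 probe sets, with the other of opposite sign and not called.

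By list, 21 of 32 neurogenesis genes rose between E10.5 and E12.5 and none fell (26 higher and 1 lower adjusted over the list alone, median 2.32, adjusted p = 5.04e-23, adjusted p = 0.332 with an estimated correlation). Of 22 pigment epithelium genes 7 rose and 2 fell (12 higher and 3 lower adjusted over the list alone, median 1.01, adjusted p = 0.000663, adjusted p = 0.591 with an estimated correlation). One of those that fell was Trpm1, a cation channel of melanocytes and retina, by 2.73 (SE 0.55, adjusted p = 0.0191) on 1 of its 4 probe sets, with 2 of opposite sign and not called. Of 20 mesenchyme genes 5 rose and none fell (12 higher and 2 lower adjusted over the list alone, median 0.99, adjusted p = 8.35e-06, adjusted p = 0.332 with an estimated correlation), and Dlx1, which the forebrain list also holds, was one of them. Of 32 basement membrane and matrix genes 6 rose, 26 did not pass and none fell (8 higher and 3 lower adjusted over the list alone, median 0.22, adjusted p = 0.0284, adjusted p = 0.799 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.0683). Among them Efemp1, a fibulin, rose by 3.57 (SE 0.43, adjusted p = 0.00093), Npnt by 2.33 (SE 0.37, adjusted p = 0.00494), and the basement membrane genes Col4a5 and Nid2 by 1.41 and 1.29, the first on 1 of 2 probe sets with the other of opposite sign and not called. Of 24 hypoxia and glycolysis genes 4 fell, 20 did not pass and none rose (6 lower and 1 higher adjusted over the list alone, median -0.53, adjusted p = 0.0277, adjusted p = 0.849 with an estimated correlation). These included Aldoa, a glycolytic aldolase, at -2.23 (SE 0.46, adjusted p = 0.0212) and Hk2, a hexokinase, at -1.19 (SE 0.25, adjusted p = 0.0247). In the coloboma gene list, whose members cause failure of fissure closure when mutated, 2 of 34 rose, Cyp1b1 and Smoc1, and 4 fell, among them Sall1 at -2.28 (SE 0.43, adjusted p = 0.0132) and Sall4 at -1.38 (SE 0.27, adjusted p = 0.0165). Adjusted over that list alone 3 were higher and 6 lower, and the list was not called (median -0.38, mean -0.18, adjusted p = 0.626).

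Some progenitor and Notch genes, in lists that share members, were also higher at E12.5 than at E10.5. Of 24 progenitor genes 7 rose (9 higher and 1 lower adjusted over the list alone, median 0.55, adjusted p = 4.86e-05, adjusted p = 0.593 with an estimated correlation), with Rorb at 3.45 (SE 0.39, adjusted p = 0.000629). Of 21 Notch genes 7 rose (9 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.000538, adjusted p = 0.591 with an estimated correlation), and of 12 cell cycle exit genes 3 rose (8 and 1 adjusted over the list alone, median 0.84, adjusted p = 6.14e-05, adjusted p = 0.332 with an estimated correlation). Of 9 neural crest glia and melanoblast genes 3 rose (3 adjusted over the list alone, median 0.30, adjusted p = 0.0184, adjusted p = 0.556 with an estimated correlation). The 26 ribosomal genes (median -0.53, 1 fell, 1 lower adjusted over the list alone, adjusted p = 0.0184, adjusted p = 0.881 with an estimated correlation) and 34 oxidative phosphorylation genes (-0.47, 0 called, 0 adjusted over the list alone, adjusted p = 0.0381, adjusted p = 0.921 with an estimated correlation) were lower. Relative to all genes these were -0.43 and -0.37, and -0.12 and -0.24 after quantile normalization, where the medians were -0.20 and -0.31 and both lists stayed called. Quantile normalization ended the calls of 19 FGF genes (2 rose, 3 higher and 1 lower adjusted over the list alone, median 0.22, adjusted p = 0.0294, adjusted p = 0.593 with an estimated correlation), 19 macrophage genes (1 rose and 1 fell, 3 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.0261, adjusted p = 0.535 with an estimated correlation) and 12 cartilage genes (0 called, 4 lower adjusted over the list alone, median -0.38, adjusted p = 0.0184, adjusted p = 0.685 with an estimated correlation).

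In all, 1255 probe sets passed between E10.5 and E12.5, 833 higher (598 genes) and 422 lower (308 genes), against 5993 at an unadjusted p below 0.05. The share that was higher was 66.4% as deposited, 61.0% of 1646 after quantile normalization, 56.8% of 1756 after median centring and 51.6% of 790 with the Gapdh covariate. The count was 209 without E12.5 B (89.5% higher), 670 without E12.5 A (80.7%), 685 without E11.5 B (78.1%) and 1610 without E10.5 B (53.7%). Of 26 called probe sets of the named genes, 17 stayed called whichever array was left out. Without E12.5 B, Hmga2 (adjusted p = 0.249), Cdh6, Crispld2, Hbb-bh1 and Eif4ebp1 were no longer called, and without E12.5 A Eif4ebp1 was also lost. Nefl was lost without E10.5 A or E10.5 C. The 26 were again of the largest rises and falls and the fissure closure genes, so list members such as Efemp1 and Trpm1 were not followed. The F test for any stage difference called 788 probe sets, 383 without E11.5 B and 189 without E12.5 B, against 6618 at an unadjusted p below 0.05.

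Genes tied to fissure closure before the data were examined were read at every stage. Zfp503, a zinc finger gene of the fissure margin, was lower at E12.5 than at E10.5 on both of its probe sets, by -1.98 (SE 0.36, adjusted p = 0.0121) and by -2.65 (SE 0.31, adjusted p = 0.000686). The first went from 10.9 ± 0.28 (SD, n = 3) through 10.1 ± 0.25 (SD, n = 3) to 8.93 ± 0.72 (SD, n = 2), and its call was lost without E12.5 B (adjusted p = 0.286), while that of the second held in each leave-one-out fit. Its relative Zfp703 was not called, at 6.08 ± 0.15 (SD, n = 3), 6.05 ± 0.20 (SD, n = 3) and 5.57 ± 0.25 (SD, n = 2), and its change from E10.5 to E11.5 of -0.02 became 0.08 after quantile normalization. Ntn1 fell from E11.5 to E12.5 by 2.47 (SE 0.30, adjusted p = 0.00158), whereas its change of -1.56 (SE 0.27) from E10.5 to E11.5 did not pass (adjusted p = 0.0615). Cdh4, the retinal cadherin, rose from E11.5 to E12.5 on both probe sets, by 2.44 (SE 0.30, adjusted p = 0.00158) and 2.38 (SE 0.29, adjusted p = 0.00164).

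Vax1, a homeodomain factor of the optic stalk, fell 2.82-fold (log2 SE 0.34, adjusted p = 0.032) from E10.5 to E12.5 on 1 of its 2 probe sets. The other, at -0.999 (SE 0.26, adjusted p = 0.0501), did not pass. That call was lost in 5 of 8 leave-one-out fits, without E10.5 A, E10.5 C, E11.5 B, E12.5 A or E12.5 B (adjusted p up to 0.202). Chd7, a chromatin remodeller, rose by 1.43 (SE 0.27, adjusted p = 0.0226) from E11.5 to E12.5 on 1 of 2 probe sets, and the brighter one, at 0.45 (SE 0.42), did not pass. From E10.5 to E12.5 that probe set was higher by 1.06 (SE 0.27, adjusted p = 0.0489), a call kept in 1 of 8 leave-one-out fits, and the brighter one was of opposite sign. The call from E11.5 to E12.5 was lost without E11.5 A, E11.5 B, E12.5 A or E12.5 B (adjusted p up to 0.24). Mitf, the master regulator of pigment cells, had a bright probe set that was not called, at 10.4 ± 0.57 (SD, n = 3), 10.4 ± 0.69 (SD, n = 3) and 9.22 ± 0.77 (SD, n = 2). A dim one near a log2 signal of 4 fell by 1.05 (SE 0.20, adjusted p = 0.0207) from E11.5 to E12.5, a call lost without E11.5 A, E11.5 B, E12.5 A or E12.5 B (adjusted p up to 0.349). Vax2, Pax6, Aldh1a3, Bmp7 and Lmx1b were not called in any pairwise comparison. The brightest Pax6 probe set read 10.5 ± 0.74 (SD, n = 3), 10.8 ± 0.86 (SD, n = 3) and 12.1 ± 0.29 (SD, n = 2), and that of Aldh1a3, a retinoic acid-synthesizing enzyme of the ventral cup, read 11.7 ± 0.53 (SD, n = 3), 11.6 ± 0.70 (SD, n = 3) and 11.7 ± 0.74 (SD, n = 2). A second bright Aldh1a3 probe set read 10.5 ± 0.39 (SD, n = 3), 10.2 ± 0.28 (SD, n = 3) and 9.25 ± 0.94 (SD, n = 2). Its change from E10.5 to E12.5 was -1.25 (SE 0.41, limma adjusted p = 0.107), so the Aldh1a3 probe sets differed.

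Of the 16 measured genes in the list of ventral optic cup and optic stalk, 3 rose (Cdh4, Bmpr1b and Smoc1) and 1 fell (Ntn1) from E11.5 to E12.5, with 3 higher and 2 lower adjusted over the list alone. Bmpr1b, a BMP receptor of the ventral retina, rose by 1.60 (SE 0.30, adjusted p = 0.0212), and Smoc1, a calcium-binding matrix protein, rose by 1.45 (SE 0.25, adjusted p = 0.0138). The list was not called (adjusted p = 0.869, median 0.12 and mean 0.17 with camera's direction down). From E10.5 to E12.5 3 of its genes rose and 3 fell (3 higher and 4 lower adjusted over the list alone), and it was not called (median -0.24, adjusted p = 0.684). Among the 34 axon guidance genes, 4 rose and 2 fell from E11.5 to E12.5, both over all probe sets and adjusted over the list alone. Epha5, an ephrin receptor, rose by 2.86 (SE 0.34, adjusted p = 0.00113), and Sema3e, a semaphorin, fell by 1.73 (SE 0.23, adjusted p = 0.00258) on 1 of 2 probe sets, with the other of opposite sign and not called. That list was not called either (adjusted p = 0.323, median -0.05, mean 0.12).

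**Figure D2:**
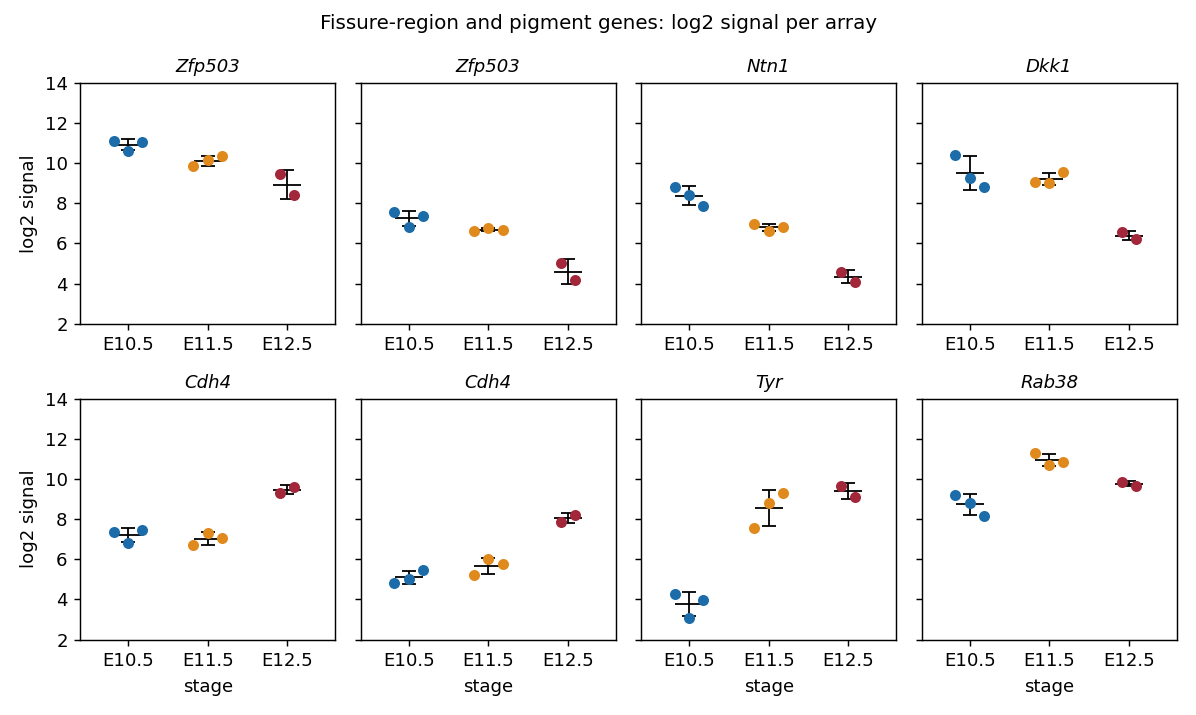
Log2 signal (vertical axis) of fissure-region and pigment genes by stage (horizontal axis), with 1 point per array and bars for the mean ± SD of 3, 3 and 2 arrays; Zfp503 and Cdh4 have 2 probe sets each. Ntn1 and both Zfp503 probe sets have their lowest values on the E12.5 arrays, both Cdh4 probe sets their highest, and Tyr lies at 4.25 or lower on the E10.5 arrays and at 7.57 or higher on the others.

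A contrast of E11.5 with the mean of E10.5 and E12.5 asked which genes differed at E11.5 from the mean of the other stages, which a change at 1 of those stages alone can also bring about. Igf1, the insulin-like growth factor, was higher at E11.5 by 2.03 (SE 0.35, adjusted p = 0.0449), and Fap, a fibroblast surface protease, by 1.87 (SE 0.29, adjusted p = 0.0318). Rab38 was higher by 1.71 (SE 0.29, adjusted p = 0.0428), at 10.96 ± 0.29 (SD, n = 3) against 8.73 ± 0.53 (SD, n = 3) at E10.5 and 9.77 ± 0.13 (SD, n = 2) at E12.5. Parm1, a membrane mucin, was higher by 1.80 and the noncoding A930001A20Rik by 1.32. Fgf15 was lower at E11.5 by -2.39 (SE 0.31, adjusted p = 0.0125), Tox3, a chromatin-associated factor, by -1.78 (SE 0.23, adjusted p = 0.0132), and Lin7a, a scaffold protein of cell junctions, by -1.88 (SE 0.25, adjusted p = 0.0135). Lin7a read 6.49 ± 0.02 (SD, n = 3), 6.13 ± 0.23 (SD, n = 3) and 9.54 ± 0.71 (SD, n = 2) by stage, so most of its contrast came from E12.5, and Fgf15 read 8.26 ± 0.26 (SD, n = 3), 7.27 ± 0.42 (SD, n = 3) and 11.06 ± 0.84 (SD, n = 2). The noncoding Miat was lower by -1.84 and Ppp1r17, a phosphatase inhibitor, by -2.77. In all 65 probe sets passed, 17 higher and 48 lower, against 4487 at an unadjusted p below 0.05. The share that was higher was 26.2% as deposited, 62.2% after quantile normalization and 51.5% after median centring. All 10 named calls were lost without E11.5 A, and the count was 18 without E11.5 A, 11 without E11.5 B, 24 without E11.5 C, 32 without E12.5 B and 228 without E12.5 A.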

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

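Leaving out the 2 arrays that stand apart (E10.5 C and E11.5 A) and gene-by-gene array weights were chosen only after the data were seen. The 76 called results followed here are of the largest rises and falls and the fissure closure genes, not of other list members. They kept their direction wherever they were fitted. This leaves out 12 that the stricter filter removed, and the fits of 2 stages, run for counts only. In these results no array overlapped between the stages compared. Leaving out or weighting arrays, pseudocounts, filters and the trend therefore could not reverse them. Of the 76, calls were lost for 24 with a pseudocount of 64, 23 with the covariate, 23 with no trend, 5 with quantile normalization, 5 with no filter, 1 with median centring and up to 32 without 1 array (E12.5 B). Of 41 list calls, 14 were lost with quantile normalization, 10 with the covariate, 10 with no filter and 5 with the mean of a gene's probe sets. The cause of these losses, and of the changes with processing given below, was not tested. Leaving out an E12.5 array leaves 1, which is then assumed to vary like the other groups. Signal over background was not known, which limits what can be said of dim genes.

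Over leave-one-out fits the counts ranged from 189 to 1046 (any stage difference), 5 to 56 (E11.5 vs E10.5), 114 to 905 (E12.5 vs E11.5), 209 to 1610 (E12.5 vs E10.5), 11 to 228 (middle-stage contrast) and 35 to 44 called lists. In the same order, array weights gave 14230, 5017, 12520, 3371 and 12051 probe sets, and 11538, 2733, 10431, 3054 and 9145 gene by gene. These weights put E11.5 B at 218 and 11.8 with most others under 1, so the fit rests on that array. With the replicate letter as a block the counts were 351, 5, 280, 531 and 21, and 29 of the 76 named calls did not pass. Same-letter arrays did not deviate together (residual correlations from -0.39 to 0.13). This gives no sign that the letters pair the arrays, but so few arrays cannot exclude it. The block also costs degrees of freedom.

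For E11.5 vs E10.5, median centring gave 80, a pseudocount of 64 gave 0, no trend 6, the covariate 152, the 2 stages alone 15 and leaving out the 2 arrays that stand apart 103. For E12.5 vs E11.5 the covariate gave 73. For E12.5 vs E10.5 the covariate gave 790 and the 2 stages alone 509. The middle-stage contrast gave 99 with median centring, 40 with a pseudocount of 64, 42 with no filter, 36 with the stricter filter, 15 with no trend and 35 with the covariate. The F test gave 1195 without the 2 arrays. An estimated correlation left 0 of 41 list calls and fry 8, and for retinal neurogenesis at E11.5 vs E10.5 fry gave the direction as down where camera gave up, with the same median of -0.13.

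The other reversals were in probe sets not called. For E11.5 vs E10.5, quantile normalization gave Zfp703 0.082, Aldh1a3 0.81, Cdh4 0.018 and Mitf 0.68, median centring gave Zfp703 0.070 and Mitf 0.061, and the covariate gave Bmp7 0.014, Aldh1a3 0.54 and Mitf 0.64. Array weights gave Cdh4 0.24 (0.21 gene by gene), and leaving out the 2 arrays gave Lmx1b -0.017, Cdh4 0.11 and Mitf 0.015. For E12.5 vs E11.5, the covariate gave Pax6 -0.20, Lmx1b 0.14, Aldh1a3 -1.19 and Vax2 -0.30, quantile normalization gave Aldh1a3 -0.60 and Vax1 -0.21, median centring gave Vax1 -0.023, array weights gave Chd7 -0.0019 and leaving out the 2 arrays gave Aldh1a3 -0.23. For E12.5 vs E10.5, the covariate gave Lmx1b 0.19 and Aldh1a3 -0.65, median centring gave Aldh1a3 -0.018, array weights -0.080 (-0.087 gene by gene) and leaving out the 2 arrays -0.25.

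Leave-one-out ranges that crossed 0 were, for E11.5 vs E10.5, -0.13 to 0.73 (Pax6), -0.095 to 0.091 (Zfp703), -0.45 to 0.25 (Aldh1a3), -0.23 to 0.44 (Vax2) and -0.37 to 0.32 (Mitf). For E12.5 vs E11.5 the range was -0.38 to 0.66 (Aldh1a3), and for E12.5 vs E10.5 it was -0.12 to 0.12 (Lmx1b) and -0.50 to 0.54 (Aldh1a3).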

Other observations

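The 2 melanin tests and the scaled check of the neural retina test were written only after the result was seen, as was a hand-picked choice of 16 forebrain genes, whose median of -0.062 decided nothing.

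Afp rose by 5.98 in the fissure at E12.5, and its usual sources are liver and yolk sac. RNA of those tissues in the E12.5 pools could carry it. As a group, 30 hepatic and yolk sac genes did not rise, with a median change of -0.014 (quartiles -0.18 to 0.076). These genes were an added list, not one of the lists fixed before the data were examined. Most of them stayed at low signals on every array, so this median cannot exclude a small amount of such RNA. Albumin, 1 of the 30, rose by 1.48, from 3.51 on the E11.5 arrays to 4.98 on the E12.5 arrays. A direct stain for Afp in the fissure could settle where it is made.

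Of 32 neurogenesis genes 17 rose at E12.5 (adjusted p = 0.397 for the list with an estimated correlation), and 3 other readings than onset in the fissure were tried. For forebrain tissue, 21 forebrain markers outside that list did not rise as a group, with a median of -0.056 (quartiles -0.12 to 0.027), which met a bound set beforehand. Most of them stayed at low signals on every array, so their median cannot exclude a share of forebrain tissue. Dlx1 at 4.89 and Dlx2 at 2.53 were exceptions among them. Of all 22 (median -0.055), the 1 that the neurogenesis list also holds, Isl1, rose by 3.60. Scale of the kind that quantile normalization removes is excluded as the whole cause, with a median of 2.48 after it (quartiles 1.48 to 3.08). More neural retina in the E12.5 captures may explain part of it and stays open, because the neurogenesis median exceeded that of progenitor genes by 1.37 as deposited, within the spread of 1.60 between the list's quartiles, but by 1.88 after quantile normalization, beyond that spread (1.60 there also), so the outcome turns on scaling.

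Of 22 melanin genes 4 rose at E11.5 (adjusted p = 0.332 for the list with an estimated correlation). More pigment epithelium in the capture might do this and stays open, since the 6 members already above a log2 signal of 8 at E10.5 had a median change of 0.53 with quartiles from -0.37 to 1.64. After quantile normalization these 6 changed by 0.68 (Mitf), 1.67 (Dct), 2.42 (Pmel), -0.02 (Trpm1), 2.95 (Rab38) and 0.27 (Otx2). The rise remained after quantile normalization, in a test of scale rewritten after its values were seen. The E11.5 arrays had the lower upper end of signal, and quantile normalization raised the change of every member. A large lowering could hardly arise, so this test does not exclude scale. That normalization moved the 22 members, relative to all genes, by a median of -0.10 (quartiles -0.13 to 0.33), against a list shift of 1.28. The list stayed called (adjusted p = 1.61e-12, preset correlation) with a median of 1.23 and quartiles from 0.19 to 2.20.

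Relabelling the arrays tested whether groupings other than stage could give as many calls. For E11.5 vs E10.5, 1 of 10 splits, the real one, reached 34 calls and the next had 3, and 13 lists were called against at most 9, but 10 splits cannot give a share under 0.05. For the F test 2 of 100 splits, drawn from 280, reached 788, the real one and 1 other, and the others had a median of 0. That other split gave 1083, and the next gave 305. It kept the E12.5 pair together but exchanged E10.5 C and E11.5 C. The F test thus does not show that the earlier arrays group by stage.

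The sex-linked Xist signal ranged from 3.01 to 11.3 between pools, and Eif2s3y from 4.79 to 9.25, so the pools differ in the sex of their embryos.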
